A study of Mus musculus with 3 samples.

How the data were processed

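The deposited values are unnormalized UMI counts per gene and barcode, 1 matrix for each of 3 libraries, made with Cell Ranger 3.0.2 per the file headers and the labels' protocols. The submitters' processing notes name Cell Ranger 3.1 and Seurat 3.2.0 instead, and which version made the matrices is not settled by the sources used here. Per the labels' protocols, E0771 cells with vector, wild-type Malt1 or paracaspase-deficient Malt1 were grown in mammary fat pads of C57BL/6 mice, about 10000 live CD45+ cells were sorted by flow cytometry from the tumours of each, and libraries were made on the 10x Genomics platform and read paired-end on a HiSeq X instrument. The labels name a V(D)J reagent kit and a 3' v2 protocol side by side, which count different ends of transcripts. Per the submitters' processing notes the genome is GRCh38 (hg38), yet all 32285 features carry mouse identifiers, and the mouse build and the number of mice per library are not given in the sources used here. Gene positions and transcript lengths below are from GENCODE vM21 (GRCm38, 1-based), in which 32158 of the genes (99.6%) have a transcript.

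The matrices list 6794880 barcodes each, of which 1607657 (vector), 1572771 (wild-type) and 1426703 (paracaspase-deficient) hold a UMI, with totals of 85864938, 120180573 and 99397080 UMIs. Cells were called with own code that follows 2 published steps. Barcodes above the 0.99 quantile of the top 3000 totals divided by 10 were called, and those from 500 UMIs up to that limit were compared with the RNA of barcodes of up to 100 UMIs by 10000 Monte Carlo draws at an FDR of 0.01. This called 11368, 12471 and 10874 cells. The plateau of empty droplets lies higher than the 100-UMI limit, at medians of 220, 287 and 231 UMIs, so the comparison passes most barcodes of 500 UMIs or more. Cells with under 250 genes or a mitochondrial share of 10% or more were dropped, the latter removing 1475, 956 and 1303 cells. Doublets were scored by the Scrublet method, with 2 simulated doublets per cell, in each library alone. It removed 196, 280 and 239 cells (1.98%, 2.43% and 2.50%), which left 9696, 11234 and 9330 cells holding 78.1%, 81.1% and 80.3% of UMIs before doublet removal.

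Cells of all libraries were clustered together, without batch correction, on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1 (igraph 0.11.9). Clusters took the class of a fixed marker list with the highest score if at least 3 of its markers were found in 25% of their cells and no other class had more markers in the top 10 genes. A cluster with a median UMI count over 3-fold below that of its libraries also needed 1 of its own markers in the top 10. The rest stayed unnamed. T cells were clustered again in the same way. After the clusters were seen, 3 details of naming were altered: T subset markers also count as T cell markers, the required difference in detection was lowered from 1.5-fold to any, and fibroblast, epithelial and endothelial clusters became 1 non-immune class. Which class each gene list is read in was set after the clusters but before any list value was seen. The main measures, gene lists and most alternatives were chosen before the data were examined, but 5 of the 9 tests of explanations only after the results were seen.

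Levels are summed counts of a class in a library, scaled to CPM of that class. Gene ratios add 0.5 counts to each side, and gene levels, gene ratios and shares have exact Poisson or binomial 95% intervals. Ratios of shares add no counts, and their intervals use a normal approximation on the log2 scale. Intervals of list medians come from repeated Poisson draws of the counts and need not be centred on the median. As there is 1 library per group no test or count of differing genes is made. Classes with fewer than 100 cells in a library are left out of gene levels. In each of the 4 immune classes with the most cells in their smallest library, the text names the 3 genes highest and the 3 lowest by the bound of the interval nearer to 0. Each has at least 30 UMIs, 50 CPM, detection in 5% of cells and a ratio of 1.5, and at least 0.5 of its free RNA level, in the library where it is higher. Receptor and immunoglobulin segments, ribosomal, mitochondrial, haemoglobin, Xist, Y-linked, Gm and Rik genes are not named by this rule. Against a count of 0 a ratio is given as a lower bound over 3 counts. A set of 30 genes, picked after the data were seen, is at least 2-fold higher in the paracaspase-deficient library than in either other library in each of 5 classes, with at least 10 UMIs in each. Gene lists are read in 1 class each, apart from a few readings in other classes that were picked after the values were seen: the median log2 ratio of members with at least 10 UMIs over both libraries, and its percentile among 10000 random lists matched on expression in 20 bins. Up to 4 members with the largest ratios serve as examples. Mx1 and Aldoa, members of the interferon and hypoxia lists, carry no symbol in the files.

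The lists are interferon response, interferon gamma targets, MHC class II, MHC class I, NF-kB and inflammation, immunosuppressive myeloid, complement and lipid, chemokines, hypoxia and glycolysis, and neutrophil granules in phagocytes. Proliferation, exhaustion, regulatory T effector, naive and memory, and Malt1 partner lists are read in T cells. Cytotoxic effectors are read in NK cells, checkpoint ligands in dendritic cells, and dissociation stress, ribosomal protein and mitochondrially encoded genes in B cells.

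Alternatives chosen in advance were a call of every barcode of 1000 UMIs or more, mitochondrial limits of 5% and 20%, doublets kept, Leiden resolutions 0.5 and 2, clustering without the list genes, and a class per cell. For levels they were median-of-ratios scaling, equal weight per cell, free RNA subtraction, cells of 2000 UMIs or more, a pseudocount of 5 CPM and other UMI minimums. The free RNA share used in the subtraction was estimated as 5.80%, 10.7% and 5.54% of phagocyte UMIs from 10 foreign markers, by their lower quartile; the median was given up after its values were seen. Chosen after the data were seen were denominators without B cells, without B and T cells, or without unnamed and non-immune cells. So were T sub-cluster 8 added to the regulatory T cells, phagocytes without cluster 22, list members above the free RNA level only, and removal of a quadratic trend of log2 ratio over transcript length and GC share, fitted on genes with at least 50 UMIs. Under the 5% mitochondrial limit the doublet threshold failed in the vector and paracaspase-deficient libraries, so the main threshold was kept, which in the vector library marked only 0.320% of cells.

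The code was checked on simulated data. With real class depths and 8067 genes in phagocytes for wild-type against vector, the interval excluded 0 for 92.5% of genes at a true 1.5-fold and 100% at 2-fold and 4-fold, and for 4.50% of unaltered genes. For paracaspase-deficient against vector (8348 genes) it was 85.0%, 97.5% and 100%, and in NK cells for wild-type against vector (6004 genes) 85.0%, 100% and 100%. Of 40 unaltered lists, 2, 6 and 3 fell outside percentiles 5 to 95 in phagocytes for wild-type over vector, paracaspase-deficient over vector and wild-type over paracaspase-deficient. Of 400 barcodes of free RNA alone, 2, 0 and 0 were called, and of 100 phagocytes thinned to low depth 100, 57 and 90. Of 100 thinned B cells 67, 28 and 51 were called, so shallow B cells are lost more in the Malt1 libraries, the same way as the B cell shares differ. Of 100 doublets planted in the wild-type library, 75 of B cell with phagocyte, 23 of T cell with phagocyte and 0 of B with T cell were marked, so most doublets of T cells remain. Both simulations were redesigned on thinned real cells after a first version. Code ran on Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, on 1 thread with seed 1.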

Results

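E0771 mouse breast tumour cells carrying an empty vector, wild-type Malt1 or paracaspase-deficient Malt1 were grown in the mammary fat pad, and live CD45+ cells of the tumours were sequenced as 1 library per group. Malt1 is a scaffold and protease that links antigen receptors to NF-kB signalling, so the 3 comparisons ask how the immune cells differ when the tumour cells carry more Malt1, with or without its protease activity. After filtering, 9696 vector, 11234 wild-type and 9330 paracaspase-deficient cells remained, and the median cell that passed the filters held 4811, 6282 and 6198 UMIs. With 1 library per group no difference below has a replicate check, and each 95% interval covers counting error only. The wild-type and paracaspase-deficient comparisons share the vector library, so a trait of that library alone appears in both.

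B cells, the lymphocytes of the antibody lineage, made up 59.3% (58.3 to 60.3) of the CD45-sorted vector cells, 14.7% (14.1 to 15.4) of the wild-type cells and 20.8% (1942 of 9330) of the paracaspase-deficient cells. Their share was 4.03-fold lower (3.84 to 4.22) in the wild-type and 2.85-fold lower (2.73 to 2.98) in the paracaspase-deficient library than in the vector library. Mononuclear phagocytes, the monocytes and macrophages, went the other way at 5.04% (4.62 to 5.50), 41.1% (40.2 to 42.0) and 33.7% (32.8 to 34.7), or 8.15-fold (7.46 to 8.91) and 6.69-fold (6.10 to 7.32) higher than in the vector library. Dendritic cells, which carry antigen to T cells, made up 1.31% (1.09 to 1.56), 9.23% (8.70 to 9.78) and 6.57% (6.08 to 7.09). NK cells, the innate killers of stressed cells, made up 2.81% (2.49 to 3.15), 6.35% (5.90 to 6.81) and 5.61% (5.15 to 6.09).

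T cells made up 22.2% of the vector, 13.3% of the wild-type and 21.5% of the paracaspase-deficient library, and plasmacytoid dendritic cells 0.609%, 1.16% and 0.750%. Neutrophils, the granulocytes of acute inflammation, made up 1.14%, 0.472% and 0.654%, and plasma cells 0.330%, 0.0801% and 0.171%. Clusters without a name held 6.21%, 11.7% and 9.25% of cells. Because shares add up to the whole, the B cell share sets the scale for the others. With B and T cells left out of the denominator, a choice made after the shares were seen, mononuclear phagocytes stay higher in the wild-type library by 1.07 log2 and NK cells become lower by −0.78 log2.

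**Figure D1:**
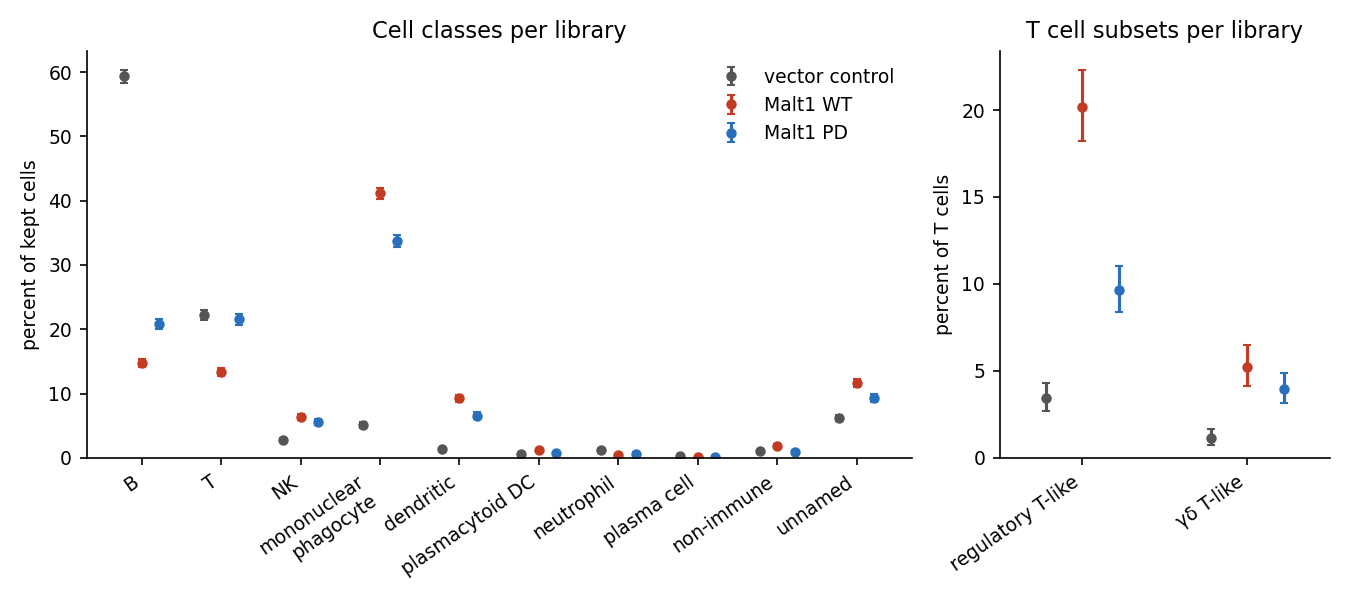
Percent of kept cells in each class, by library, and at right the percent of T cells with regulatory or gamma delta markers. Bars are 95% binomial intervals. B cells are most common in the vector library and phagocytes in the Malt1 libraries.

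Between the Malt1 libraries, B cells were 1.41-fold less common (−0.50 log2, −0.58 to −0.41) and T cells 1.62-fold less common (1.52 to 1.72) with wild-type than with paracaspase-deficient Malt1. Mononuclear phagocytes were 1.22-fold (1.18 to 1.26), dendritic cells 1.41-fold (1.28 to 1.55) and plasmacytoid dendritic cells 1.54-fold (1.16 to 2.06) more common. The phagocyte ratio of 0.29 log2 turns to −0.033 with B and T cells left out, and the B cell ratio shrinks to −0.034 with a mitochondrial limit of 5%. Non-immune cells, mostly a tumour-like cluster with Krt8 and Rhox5, made up 1.87% of wild-type and 0.943% of paracaspase-deficient cells, against 1.02% of vector cells. These cells passed a CD45 sort, and their wild-type over vector ratio of 0.87 log2 turns to −0.20 with B cells left out of the denominator.

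Regulatory-T-like cells, which carry Foxp3 and restrain other T cells, were 3.44% (2.71 to 4.30) of 2152 vector T cells, 20.2% (18.2 to 22.3) of 1495 wild-type T cells and 9.66% (8.40 to 11.0) of 2008 paracaspase-deficient T cells. That is 5.87-fold (4.60 to 7.51) and 2.81-fold (2.16 to 3.65) above the vector library, and 2.09-fold (1.77 to 2.47) higher with wild-type than with paracaspase-deficient Malt1. With an unnamed sub-cluster that also carries Foxp3 added (123, 54 and 82 cells), a choice made after it was seen, the ratios over vector shrink from 2.55 and 1.49 to 1.38 and 0.59 log2. A T sub-cluster with Tnfrsf4 and Foxp3 held 29, 208 and 120 of these cells, and a cycling one, with no regulatory T marker among its 10 top genes, 45, 94 and 74. At the main setting the first alone is 10.3-fold (7.04 to 15.1) and 4.43-fold (2.97 to 6.62) above the vector library. These folds rest on 29 vector cells and depend on the setting. A like sub-cluster held 55, 222 and 139 cells with doublets kept and 50, 212 and 136 with a mitochondrial limit of 5%. At the lowest Leiden resolution it held 58, 255 and 156, so the folds are smaller under these settings. It stayed close at the highest resolution (30, 209 and 121) and without list genes in clustering (31, 220 and 129). Gamma-delta-like T cells, unconventional T cells with Trdc, were 1.12%, 5.22% and 3.93% of T cells, or 4.68-fold (2.97 to 7.36) and 3.53-fold (2.24 to 5.55) above the vector library. The wild-type ratio, 2.23 log2, is 1.29 with a mitochondrial limit of 5%, and with a class per cell the ratios are 0.36 and 0.26. CD4 and CD8 shares are not compared, because most naive-like T cells fell into sub-clusters held almost wholly by 1 library, and 47.2%, 56.7% and 34.3% of T cells stayed unnamed.

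Within the mononuclear phagocytes, monocytes, the blood-derived precursors, were 38.2% (33.9 to 42.7) in the vector library, 32.1% (30.8 to 33.5) in the wild-type library and 31.9% (30.3 to 33.5) in the paracaspase-deficient library. The direction depends on the filter: wild-type over vector is −0.25 log2 here but 0.13 with a mitochondrial limit of 5% and 0.079 with 20%. Among dendritic cells, the migratory type with Ccr7 and Fscn1 was 49.6%, 58.2% and 50.9%. Phagocyte clusters 2 and 3 held many cells of all groups, but the order differs: clusters 2, 3 and 22 lead in the vector library, 3, 2 and 6 in the wild-type library and 2, 5 and 3 in the paracaspase-deficient library.

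Malt1 itself (ENSMUSG00000032688, chromosome 18:65430938–65479067, plus strand) stood at 279 CPM (counts per 1e6; 275 to 283) over all vector cells, 171 (169 to 174) over wild-type cells and 285 (281 to 289) over paracaspase-deficient cells. In the tumour-like cluster (95, 198 and 81 cells) it was 34.2 (29.9 to 39.0), 48.0 (44.1 to 52.2) and 63.1 (56.3 to 70.5) CPM. Malt1 there lies below the 109, 101 and 137 CPM of free RNA in the same libraries. In mononuclear phagocytes it was 393, 174 and 291 CPM, and in dendritic cells 688, 378 and 636 CPM. B cells held 385, 305 and 435 CPM, T cells 134, 114 and 173, and NK cells 396, 273 and 461. Counts per gene do not tell the construct from the cell's own Malt1.

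NK cells (272 vector, 713 wild-type and 523 paracaspase-deficient) lay in clusters 10 and 29 in all groups. Cluster 29, cycling cells with Gzmc, Gzmd and Gzme among the 10 top genes, held 14, 98 and 73 of them. Its median cell held 17613 UMIs, against 6434 in cluster 10, so each of its cells weighs more in summed levels. How much its share adds to the folds below was not tested. The granzymes of the Gzmc to Gzme block, proteases that NK cells release into targets, were much higher in NK cells of both Malt1 libraries. Gzmd (chromosome 14:56129556–56132608) stood at 16.2, 2567 and 1248 CPM, 156-fold (112 to 232) and 75.9-fold (54.5 to 113) above the vector library. Gzme stood at 18.2, 1173 and 527 CPM, 63.5-fold (46.4 to 91.9) and 28.5-fold (20.8 to 41.4) higher. Gzmg had no count in the vector library and 727 and 508 CPM in the others, at least 479-fold and 334-fold above a floor of 3 counts (1.52 CPM) in the vector library. A minority of NK cells carries these levels: Gzmd was found in 2.57%, 33.4% and 20.5% of them and Gzmg in 14.2% and 5.16% of those of the Malt1 libraries. Gzmd was also higher over vector in the other 4 classes, and the free RNA held 10.4, 242 and 101 CPM of it. Gzmd, Gzme and Gzmg are near-identical in sequence, so how their counts divide among them is uncertain. Gzmf stood at 82.0, 1877 and 1277 CPM (22.8-fold and 15.5-fold higher) and Gzmc at 925, 7494 and 4904 CPM (8.10-fold and 5.30-fold higher). Gzmb, the main target-killing granzyme, stood at 2005, 4582 and 4726 CPM, while Gzma was close at 8881, 10100 and 9037 CPM.

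**Figure D2:**
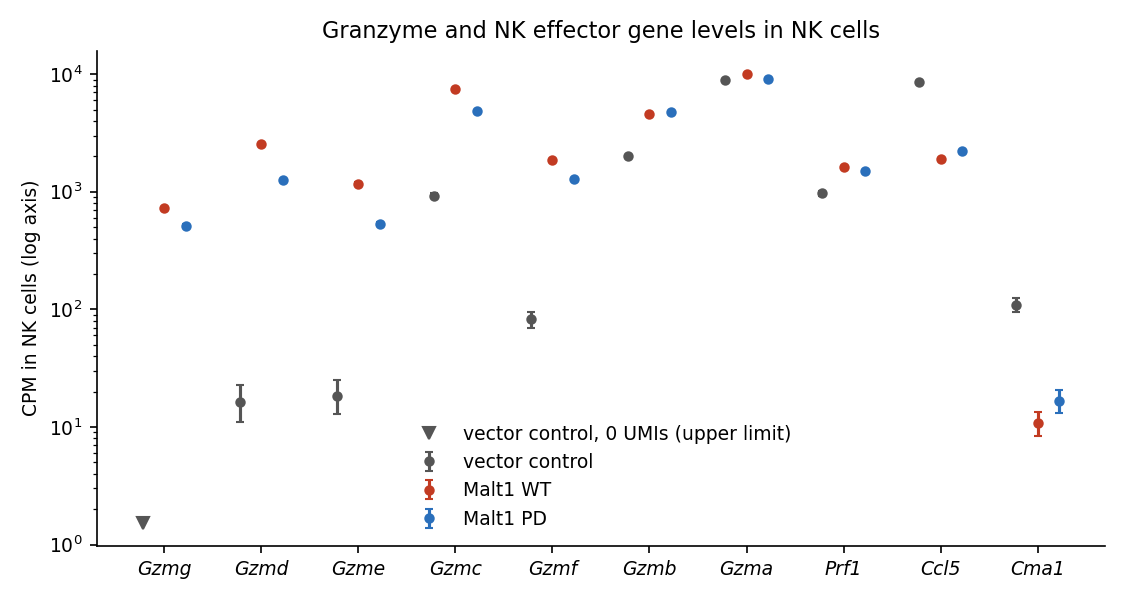
Level of 10 genes in NK cells of each library, in CPM on a log axis. Bars are 95% Poisson intervals and the triangle is the floor of 3 counts for a gene with no count. Gzmd, Gzme and Gzmg separate the libraries most and Gzma least.

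Against these, Ccl5, a chemokine that draws T cells, was lower in NK cells at 8542, 1885 and 2237 CPM, 4.53-fold lower in the wild-type and 3.82-fold lower (3.73 to 3.91) in the paracaspase-deficient library. Ccl4, a related chemokine, was 2.97-fold and 2.41-fold lower at 1252, 421 and 519 CPM. Cma1, a chymase, was 10.1-fold lower (7.75 to 13.4) and 6.58-fold lower (5.11 to 8.62) at 109, 10.7 and 16.5 CPM. The kinase gene Sgk1 was 6.47-fold lower (4.83 to 8.78) in the wild-type library at 66.8 and 10.3 CPM, the zinc-finger gene Zbtb10 6.32-fold lower (4.52 to 8.99), and the transcription factor Mef2c 4.16-fold lower (3.47 to 5.02) in the paracaspase-deficient library. Mef2c stood at 158 CPM in the vector and 37.9 in the paracaspase-deficient library, below the 249 and 80.1 CPM of their free RNA. The median gene in NK cells was lower by −0.27 log2 in the wild-type than in the vector library, and these folds stand against that shift. With gains and losses in the same list, the cytotoxic effector list of 16 genes has a median of 0.10 log2 (0.05 to 0.17) over vector for wild-type, at percentile 60.3 of random lists (−0.24 with the length and GC trend removed), and 0.05 (0.01 to 0.14) for paracaspase-deficient, at percentile 75.1.

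Wild-type set against paracaspase-deficient NK cells had more of the block: Gzmd was 2.06-fold, Gzme 2.22-fold (2.13 to 2.33) and Gzmc 1.53-fold higher. With the length and GC trend removed, Gzmd goes from 1.04 to 0.73 log2 and Gzme from 1.15 to 0.83. Ifitm1, an interferon-induced membrane protein gene, was 1.83-fold higher (1.65 to 2.04) at 175 against 95.3 CPM, and 9.62 CPM in the vector library. Its ratio goes from 0.87 to 0.545 log2 with the trend removed. Ifng, the macrophage-activating cytokine, was 1.40-fold lower. Klf2, a quiescence factor, was 5.12-fold lower (4.32 to 6.12) at 24.4 against 125 CPM, and lower in the other 4 classes too. The median gene differed by −0.18 log2 here, and the cytotoxic list by 0.03 log2 (−0.01 to 0.09), percentile 39.1.

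T cells of the Malt1 libraries carried more of the genes of activated and regulatory cells. Levels are summed over all T cells, so the larger regulatory-T-like share of these libraries enters them. Tnfrsf4, Areg and Il1r2 are top genes of the T sub-cluster with Foxp3, which held 29, 208 and 120 cells. Free RNA was estimated at 4.77%, 9.16% and 5.45% of T cell UMIs. Tnfrsf4 (OX40, a co-stimulatory receptor) stood at 118, 815 and 365 CPM in T cells, 6.93-fold higher (6.57 to 7.31) with wild-type Malt1 than in the vector library and 2.23-fold higher (2.15 to 2.32) than with the paracaspase-deficient form. Areg, a tissue-repair growth factor, stood at 14.8, 119 and 128 CPM, 8.01-fold (6.92 to 9.35) and 8.60-fold (7.46 to 10.0) higher. Gzmf was 10.1-fold higher (8.82 to 11.6) at 17.2 and 174 CPM, beside 19.6 and 309 CPM in the free RNA of the same libraries. Gzmf was found in 0.28% of vector and 16.0% of wild-type T cells, so its vector level rests on very few cells. Il1r2, a decoy receptor for interleukin 1, and Lmna, a nuclear lamina gene, were 2.56-fold (2.28 to 2.87) and 2.41-fold (2.21 to 2.63) higher with wild-type than with paracaspase-deficient Malt1. With the length and GC trend removed, Tnfrsf4 between the Malt1 libraries goes from 1.16 to 0.84 log2 and Il1r2 from 1.36 to 1.12. Lmna stays at 1.27. The T cells lie in clusters 9, 7 and 14 in the vector and paracaspase-deficient libraries but in 15, 14 and 7 in the wild-type library.

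Lower in T cells of the wild-type than of the vector library were Dusp10, a phosphatase of stress kinases (4.06-fold, 3.70 to 4.47), Jmy, an actin nucleator (3.75-fold, 3.27 to 4.33), and Tcp11l2 (3.42-fold, 3.04 to 3.86). Jmy goes from −1.91 to −1.28 log2 with the length and GC trend removed. The lymph-node homing receptor Ccr7 was 1.95-fold lower (1.87 to 2.05) in the paracaspase-deficient library, at 228 against 445 CPM, and 193 CPM in the wild-type library. Dtx1, a Notch pathway gene, was 2.38-fold lower (2.10 to 2.71) and Plcxd2 2.12-fold lower (1.95 to 2.31) in the same comparison. Dtx1 stood at 65.9 CPM in the vector and 27.7 in the paracaspase-deficient library, beside 79.8 and 7.70 CPM in free RNA. All 6 genes are lower in each of the 5 classes measured. The median gene in T cells was higher than in the vector library by 0.13 log2 with wild-type and 0.15 log2 with paracaspase-deficient Malt1.

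The regulatory T effector list, which shares genes with the markers that name those cells, has a median in T cells of 1.56 log2 (1.35 to 1.71) over vector for wild-type and 1.19 (0.96 to 1.30) for paracaspase-deficient Malt1, both at percentile 100 as a description of these libraries. Ebi3, a subunit of interleukin 35, stood at 27.8 CPM with wild-type Malt1 against 4.61 in the vector library, beside 33.3 and 12.3 CPM in free RNA, and Tnfrsf18, the receptor GITR, at 531 against 117 CPM (4.53-fold). Il2ra, the interleukin 2 receptor, was 2.78-fold higher with paracaspase-deficient Malt1. The exhaustion list, checkpoint receptors and other genes of chronically stimulated T cells, has medians of 1.38 (1.24 to 1.58) and 1.39 (1.31 to 1.57), both at percentile 100. In it Tnfrsf9 was 4.78-fold, Prdm1 4.12-fold, Cxcr6 3.79-fold and Lag3 3.69-fold higher with wild-type Malt1, and Havcr2 4.48-fold higher with the paracaspase-deficient form.

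Proliferation genes such as Ccnb1 (4.22-fold) and Ube2c (3.85-fold) were higher in wild-type than in vector T cells, with list medians of 1.20 log2 (1.11 to 1.28) and, for paracaspase-deficient Malt1, 0.90 (0.80 to 0.97), both at percentile 100. Naive and memory T genes were lower: Satb1, a chromatin organizer, by 3.05-fold, S1pr1, the exit receptor of lymph nodes, by 2.73-fold and Lef1 by 2.70-fold. Their list medians are −1.10 (−1.15 to −1.04) for wild-type and −0.53 (−0.58 to −0.48) for paracaspase-deficient Malt1, both at percentile 0. The list of Malt1 partners and substrates was lower in wild-type T cells by −0.51 log2 (−0.63 to −0.44), percentile 0.680, with the ubiquitin ligase Traf6 1.75-fold and the A20 gene Tnfaip3 1.65-fold lower. With the paracaspase-deficient form it was −0.12 (−0.19 to −0.03), percentile 2.31.

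With wild-type against paracaspase-deficient Malt1, the regulatory T effector median in T cells is 0.53 log2 (0.45 to 0.64) at percentile 100 and the proliferation median 0.33 (0.30 to 0.42) at percentile 99.95, where Birc5, a survival gene of dividing cells, is 1.77-fold higher. The exhaustion median is −0.17 (−0.27 to −0.04) at percentile 19.1, but 0.21 with equal weight per cell, with Tigit 2.42-fold and Nr4a3 1.74-fold lower. The naive and memory median is −0.56 (−0.65 to −0.53) at percentile 0.1, led by Klf2, 3.39-fold lower, and the Malt1 partner median −0.45 (−0.57 to −0.34) at percentile 0.830. Over vector, Klf2 in T cells was 1.20 log2 higher with paracaspase-deficient Malt1, against its list, and stood at −0.56 log2 with wild-type Malt1.

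**Figure D3:**
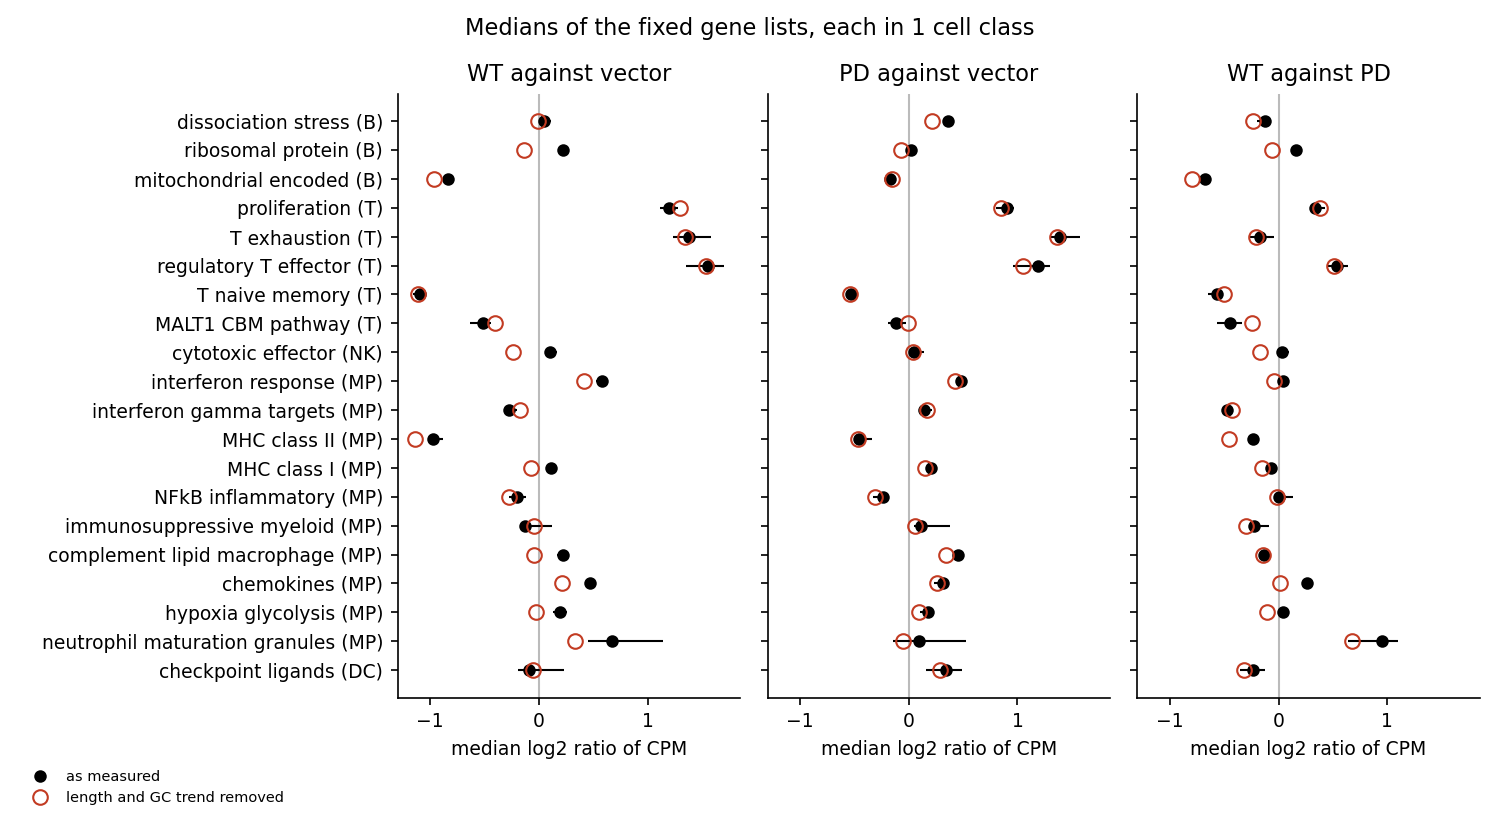
Median log2 ratio of 20 gene lists, each in its own cell class, for the 3 comparisons. Black points are as measured with 95% intervals, and red open points have the length and GC trend removed. Regulatory T, exhaustion and proliferation lists lie right and MHC class II lies left over vector.

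Mononuclear phagocytes of the Malt1 libraries (4620 wild-type and 3146 paracaspase-deficient cells against 489 vector cells) had more RNA of interferon-response genes. Isg15, a ubiquitin-like antiviral protein gene, stood at 1896, 4288 and 2801 CPM, and Cxcl10, which attracts T cells, at 1242, 2360 and 1934 CPM. Usp18 and Bst2, antiviral genes, were 1.78-fold and 1.74-fold higher with wild-type Malt1, and Ifit1 and Ifit3 1.64-fold higher with the paracaspase-deficient form. The list medians are 0.58 log2 (0.52 to 0.64) and 0.48 (0.44 to 0.53), both at percentile 100, against an all-gene median of −0.18 for wild-type. Between the Malt1 libraries the median is 0.04 (0.02 to 0.08) at percentile 28.0, turning to −0.038 with the length and GC trend removed, although Isg15 was 1.53-fold higher with wild-type Malt1.

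MHC class II genes, which present antigen to CD4 T cells, were lower in the phagocytes of both Malt1 libraries, with medians of −0.97 log2 (−0.99 to −0.88) and −0.46 (−0.47 to −0.34), each at percentile 0. H2-Eb1 stood at 1851, 944 and 1460 CPM, and Ciita, the master activator of class II genes, at 51.6 CPM in the vector and 24.4 in the wild-type library. H2-Oa and H2-DMb2, also in the list, stood at 17.9 and 29.3 CPM in vector phagocytes, beside 133 and 157 CPM in that library's free RNA. Between the Malt1 libraries the median is −0.24 (−0.25 to −0.22), percentile 8.68, with H2-Aa 1.43-fold lower, against an all-gene median of −0.17 log2. MHC class I genes differ little: the medians are 0.11 (0.09 to 0.14, percentile 57.0), 0.20 (0.16 to 0.24, percentile 97.4) and −0.07 (−0.08 to −0.05, percentile 17.5), the first turning to −0.073 with the trend removed and the last to 0.11 with median-of-ratios scaling, with the immunoproteasome gene Psmb8 1.43-fold higher with wild-type Malt1 than in the vector library.

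Interferon gamma targets had medians over vector of −0.27 log2 (−0.32 to −0.20) in wild-type and 0.14 (0.10 to 0.21) in paracaspase-deficient phagocytes, percentiles 5.95 and 92.7. The all-gene median for wild-type is −0.18, and the list is −0.066 with median-of-ratios scaling. Cxcl9, which draws effector T cells, stood at 436, 232 and 330 CPM, and Irf1 was 1.82-fold lower with wild-type Malt1. Wild-type against paracaspase-deficient Malt1 gives −0.48 (−0.51 to −0.44) at percentile 0.01, with Socs1, a brake on cytokine signalling, 3.03-fold lower, Nos2 2.70-fold lower and Iigp1 2.03-fold lower. Socs1 was 3.83-fold higher in paracaspase-deficient than in vector phagocytes, and is 1 of 30 genes that were higher in every class of that library.

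Among phagocyte genes that pass the level and free RNA limits, Scand1, a SCAN-domain protein gene, ranked first over vector at 16.4, 219 and 396 CPM (13.3-fold, 10.8 to 16.8, and 24.0-fold, 19.6 to 30.3), beside 10.8, 223 and 461 CPM in free RNA. The placental growth factor gene Pgf was 4.44-fold higher (3.46 to 5.91) with wild-type Malt1 and the mitochondrial ribosome gene Mrps24 stood at 144 against 36.0 CPM (3.47-fold to 4.66-fold higher). Lower in the wild-type library were the noncoding RNAs Kcnq1ot1 (5.20-fold, 4.49 to 6.01) and Lncpint (4.56-fold, 3.96 to 5.23), and the repressor Zbtb20 (4.11-fold, 3.52 to 4.80). With the length and GC trend of the library removed, Kcnq1ot1 goes from −2.38 to −1.54 log2, Zbtb20 from −2.04 to −1.23 and Scand1 from 3.74 to 3.12. Elmsan1 and Nr4a2, a nuclear receptor induced by activation, were 2.09-fold (1.85 to 2.36) and 1.94-fold (1.82 to 2.07) lower with paracaspase-deficient Malt1. Fdps, of sterol synthesis, was 1.98-fold (1.88 to 2.08), Pilrb2 1.80-fold (1.67 to 1.93) and the fatty-acid carrier Fabp5 1.63-fold (1.61 to 1.65) higher with wild-type than with paracaspase-deficient Malt1, Fabp5 beside 1692 and 1209 CPM in free RNA. Apart from Pilrb2, each gene of this paragraph differs the same way in all 5 classes measured, Scand1 by 3.74 to 5.02 log2 and Mrps24 by 1.83 to 2.20 for wild-type over vector.

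Chemokine genes of phagocytes had medians of 0.47 log2 (0.43 to 0.51) and 0.31 (0.24 to 0.36) over vector, both at percentile 99.95, and 0.26 (0.25 to 0.30) between the Malt1 libraries, percentile 99.6. Ccl12, a monocyte attractant, stood at 199, 632 and 423 CPM, and Cxcl3, a neutrophil attractant, at 3.62, 19.3 and 13.2 CPM. Complement and lipid genes of macrophages had medians of 0.22 (0.17 to 0.28, percentile 90.9), 0.45 (0.42 to 0.47, percentile 100) and −0.13 (−0.18 to −0.11, percentile 12.9), the first turning to −0.043 with the length and GC trend removed and the last to 0.045 with median-of-ratios scaling. Gpnmb, a lysosomal membrane protein gene, stood at 19.2, 83.3 and 74.3 CPM, beside 5.76, 245 and 171 CPM in free RNA, and the lipid receptor Trem2 at 47.2, 90.6 and 98.5 CPM, beside 8.06, 165 and 156. Abca1, a cholesterol exporter, was 2.08-fold and Cd36, below its free RNA level in both, 2.07-fold lower with wild-type than with paracaspase-deficient Malt1. Gpnmb and Cd36 are also top genes of the unnamed cluster 19 (0, 227 and 139 cells), which is not counted in this class.

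NF-kB and inflammatory genes in phagocytes had medians of −0.20 log2 (−0.28 to −0.12, percentile 9.53) and −0.23 (−0.33 to −0.20, percentile 0.1) over vector and 0.01 (−0.02 to 0.13, percentile 62.6) between the Malt1 libraries, and the first is 0.0051 with median-of-ratios scaling. Nfkb1, an NF-kB subunit, stood at 197, 108 and 136 CPM, and Tnfaip3 was 1.88-fold lower with wild-type Malt1. Immunosuppressive genes had medians of −0.13 (−0.17 to 0.12, percentile 39.4), 0.12 (0.05 to 0.38, percentile 87.3) and −0.22 (−0.27 to −0.09, percentile 13.4), and the second is −0.036 over members above their free RNA level. Within that list Arg1, which depletes arginine, stood at 0.950, 23.3 and 13.4 CPM, below its own free RNA level in the Malt1 libraries, and Tgfb1, a suppressive cytokine, at 103, 230 and 213 CPM. The unnamed cluster 19, topped by Arg1, Gpnmb and Igf1, held 0, 227 and 139 cells and is not counted in this class.

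Hypoxia and glycolysis genes of phagocytes were higher by 0.19 log2 (0.13 to 0.26, percentile 92.3) and 0.18 (0.11 to 0.21, percentile 98.3) over vector, and by 0.04 (0.01 to 0.08, percentile 69.6) between the Malt1 libraries. With the length and GC trend removed the wild-type median turns to −0.0215 and the last to −0.11. The glycolytic enzyme gene Tpi1 was 1.47-fold higher with wild-type Malt1, while Vegfa, the angiogenic factor, was 1.64-fold lower. Neutrophil granule genes had medians of 0.68 (0.45 to 1.14, percentile 99.95), 0.09 (−0.14 to 0.53, percentile 73.0) and 0.95 (0.64 to 1.10, percentile 100), and the first turns to −0.14 when members with 1 UMI are let in. Among them Lcn2, an iron-binding granule protein gene, stood at 3.81, 16.1 and 7.94 CPM. In dendritic cells the checkpoint ligand medians were −0.09 (−0.19 to 0.23, percentile 48.6), 0.34 (0.16 to 0.49, percentile 96.2) and −0.23 (−0.35 to −0.13, percentile 21.9), against all-gene medians of −0.12 for wild-type over vector and −0.16 between the Malt1 libraries. Tnfsf4, the OX40 ligand, stood at 17.5, 38.1 and 44.5 CPM in dendritic cells, and Cd80, a co-stimulator, was 1.53-fold lower with wild-type than with paracaspase-deficient Malt1.

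B cells (5753 vector, 1656 wild-type and 1942 paracaspase-deficient) lay mainly in clusters 0, 4 and 8 in the vector library, 1, 0 and 8 in the wild-type library and 0, 1 and 8 in the paracaspase-deficient library. Pxdc1 was 4.11-fold higher (3.63 to 4.64) in wild-type than in vector B cells, the sugar-pathway gene Pgls 3.27-fold (3.04 to 3.51) and the trafficking gene Unc119 3.41-fold (2.91 to 3.99). Nr4a2 was 3.95-fold lower (3.31 to 4.80), the DNA-repair nuclease gene Dclre1c 3.07-fold lower (2.48 to 3.88) and the ubiquitin ligase Nedd4 3.30-fold lower (2.66 to 4.18) with wild-type Malt1, and Nedd4 3.27-fold to 4.99-fold lower with the paracaspase-deficient form, at 14.3 against 57.5 CPM. Cd9, a tetraspanin, was 2.56-fold (2.16 to 3.07) and Impact 2.43-fold (2.04 to 2.92) lower in paracaspase-deficient B cells. Between the Malt1 libraries the splicing gene Snrnp25 was 1.94-fold (1.61 to 2.35) and Mrps7 1.53-fold (1.28 to 1.84) higher with wild-type Malt1. These are not traits of B cells alone: in the same comparisons Pxdc1, Pgls, Unc119 and Snrnp25 are higher, and Nr4a2, Impact and, with wild-type Malt1, Nedd4 lower, in all 5 classes measured.

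Stress genes induced by tissue dissociation had medians in B cells of 0.05 log2 (0.00 to 0.12, percentile 83.3) for wild-type and 0.36 (0.33 to 0.40, percentile 100) for paracaspase-deficient Malt1 over vector, and −0.13 (−0.20 to −0.07, percentile 15) between them. Jun, an early response factor, stood at 67.5, 205 and 196 CPM, and the heat-shock gene Hspa1a, below its free RNA level in every library, was 4.05-fold and 2.80-fold higher. Genes encoded in the mitochondrial genome were lower, by −0.84 log2 (−0.86 to −0.82, percentile 0), −0.17 (−0.19 to −0.16, percentile 5.13) and −0.68 (−0.69 to −0.66, percentile 0), with mt-Nd3, of respiratory complex I, at 817, 258 and 488 CPM. Ribosomal protein genes had medians of 0.22 (0.20 to 0.23, percentile 99.6), 0.03 (0.01 to 0.04, percentile 87.7) and 0.16 (0.15 to 0.18, percentile 91.6), and turn to −0.14, −0.073 and −0.065 with the length and GC trend removed.

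Among the named genes, Taf10 differed most between the Malt1 libraries in each of 4 classes. Taf10, a subunit of the basal transcription machinery (chromosome 7:105739393–105744361), was lower with wild-type than with paracaspase-deficient Malt1 by 8.25-fold in B cells, 8.89-fold (7.73 to 10.3) in T cells, 10.6-fold (9.07 to 12.6) in NK cells and 8.17-fold in phagocytes. Jund, an AP-1 factor, was lower by 5.23-fold, 4.90-fold, 6.53-fold (6.05 to 7.06) and 4.29-fold in the same classes, and Smad7, a brake on TGF-beta signalling, by 4.23-fold (3.79 to 4.73) in B cells and 4.81-fold in T cells. Over vector, Taf10 was higher with paracaspase-deficient Malt1 by 8.15-fold (7.41 to 8.97) in B cells, 10.2-fold (9.10 to 11.6) in T cells and 6.79-fold (5.87 to 7.94) in phagocytes. Bri3, a lysosomal protein gene, was 7.56-fold higher (6.77 to 8.49) in phagocytes, Tmem160 13.2-fold higher (11.3 to 15.6) in T cells, and Bcl7c and Jund 5.59-fold (4.84 to 6.46) and 4.90-fold (4.74 to 5.07) higher in B cells. Taf10, Jund, Bri3 and Tmem160 belong to 30 genes picked for being at least 2-fold higher in each of the 5 classes measured. Smad7 and Bcl7c miss that limit but are also higher than in either other library in all 5 classes. In cells not used to pick them, 30 of the 30 are higher over vector in the tumour-like cluster (median 2.07 log2) and 14 of the 15 measured in neutrophils (1.42).

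Genes with long transcripts were lower relative to short ones in the wild-type library in every class measured. In mononuclear phagocytes the median log2 ratio over vector was 0.29 for the genes with transcripts below 1916 bases and −0.66 for those above 5415 bases. Spearman's rho of transcript length with the ratio was −0.50 in B cells, −0.47 in T cells, −0.55 in NK cells, −0.58 in phagocytes and −0.53 in the tumour-like cluster. With paracaspase-deficient Malt1 over vector it was −0.10, −0.23, −0.25, −0.27 and 0.08. Malt1, with a transcript of 6404 bases, sat at percentile 52.0 in B cells, 57.5 in T cells, 62.0 in NK cells, 6 in phagocytes and 22 in dendritic cells among the 200 genes nearest to it in length. With this trend removed, the ribosomal median in B cells is −0.14, the interferon median in phagocytes 0.42, the class II median −1.14 and the regulatory T effector median 1.54 for wild-type over vector. Between the Malt1 libraries, its removal takes Snrnp25 in B cells from 0.96 to 0.61 log2 and Mrps7 from 0.62 to 0.42.

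**Figure D4:**
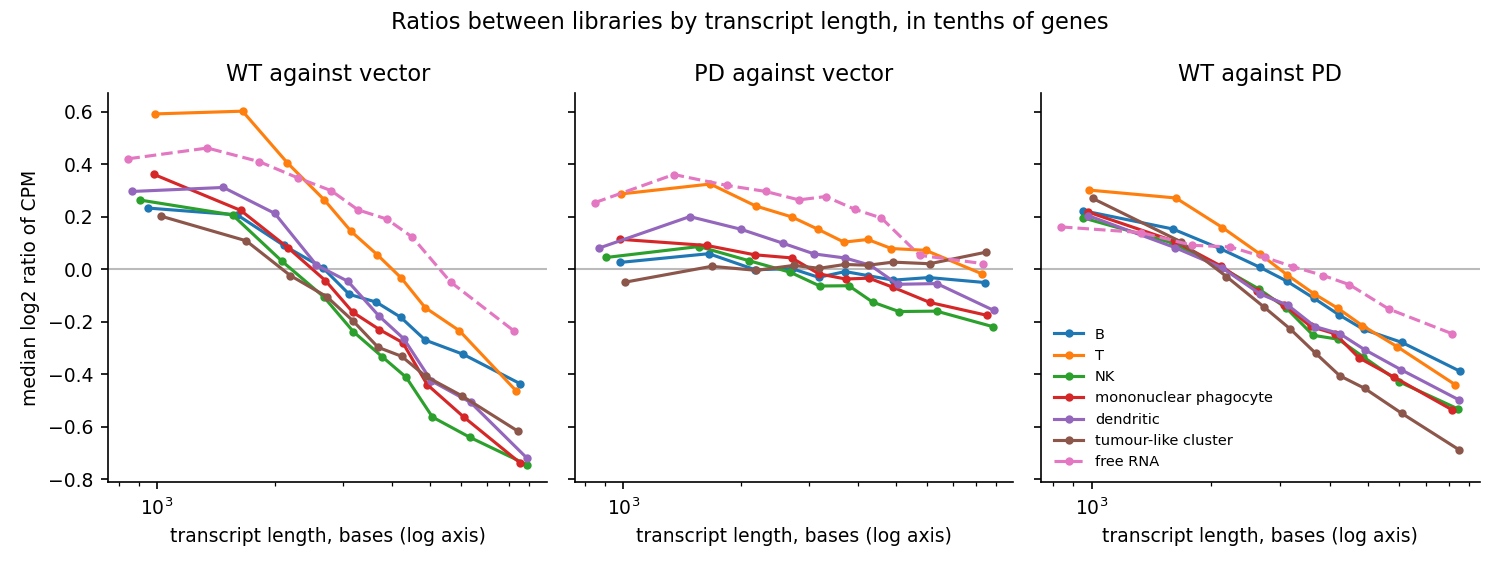
Median log2 ratio of genes grouped by transcript length, for each class, the tumour-like cluster and free RNA, in 3 comparisons. Lines slope down with length in both comparisons that involve the wild-type library and, outside the tumour-like cluster, less so for paracaspase-deficient over vector.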

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

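The tests of GC share alone, of extra B and T cells, of the mitochondrial filter, of free RNA in the paracaspase-deficient library and of a library-wide effect were chosen only after the results were seen.

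Cells of cluster 19, with Arg1, Gpnmb and Igf1, included none from the vector library at the main setting (upper limit 0.0309%). They made up 2.02% of wild-type and 1.49% of paracaspase-deficient cells. They drew attention as cells without a class that differ between groups. Macrophage markers sum to 4290 and 4092 CPM in them, against 130 and 145 CPM of T cell and 85.5 and 68.1 CPM of B cell markers, and the median cell holds 47353 UMIs. Their markers are those of macrophages, though the marker rule left them unnamed, and the difference itself was not tested.

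Cluster 27 carries Tnfrsf4, Ctla4 and Ikzf2 of regulatory T cells and, at 6816 CPM in the wild-type library, macrophage markers. It made up 0.0619% of vector, 1.05% of wild-type and 1.24% of paracaspase-deficient cells. Pairs of a regulatory T cell with a macrophage in 1 droplet may account for it, and only 23 of 100 planted T cell and phagocyte doublets were marked in the simulation. With the marked doublets kept and the cells clustered again, the regulatory-T-like ratio of wild-type over vector is 2.13 log2 instead of 2.55. The T sub-cluster with Tnfrsf4 and Foxp3 then holds 55 instead of 29 vector cells. As only marked doublets were added back, this cannot speak to unmarked pairs. Cluster 33, cycling cells with Hist1h1b and Mki67, was 0.338% and 0.407% of the Malt1 libraries (0.0619% in vector), and cluster 34, with Retnla, Lyz1 and Lpl, 0.320% and 0.214% (0.0309% in vector). These differences were picked because the clusters have no class, and they were not tested.

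Interferon gamma targets in phagocytes had medians over vector of −0.27 log2 for wild-type and 0.14 for paracaspase-deficient Malt1, and the first is −0.066 with median-of-ratios scaling. They were picked because the medians differ in sign, and this was not tested.

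Longer transcripts are lower relative to shorter ones in every class of the wild-type library, and Malt1 is long. A length bias of that library predicts the same slope in cells not looked at before, and the weakest of 5 such sets, the neutrophils, has a rho of −0.205. Malt1 has a median percentile of 52.0 among genes of like length over 5 classes, so its lower level in B, T and NK cells is consistent with the same bias. In phagocytes it sits at percentile 6 (−1.18 log2 against −0.59), so a part there stays open. GC share alone is argued against by a partial rho of length of −0.54 given GC, and what made the bias stays open.

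B cells are far more common in the vector library. Extra B and T cells alone would leave the ratios among all other classes alike. For wild-type over vector, phagocytes per dendritic cell are alike (0.21 log2, −0.09 to 0.51; 0.41, 0.11 to 0.72, for paracaspase-deficient Malt1), but phagocytes per NK cell differ by 1.85 log2 and per neutrophil by 4.31, and a looser mitochondrial filter leaves the B cell ratio at −1.91. Splenic cells in the vector sample are a candidate explanation: a marginal zone B cell list (Cr2, Cd1d1, Fcrl5 and others) is lower by −0.92 log2 with wild-type and −1.21 with paracaspase-deficient Malt1. Rapgef4 of that list goes the other way, at 9.38 CPM in vector, 15.7 in wild-type and 17.4 in paracaspase-deficient B cells. Tm6sf1 stands at 73.5, 64.6 and 76.0 CPM. Whether a lymph node of the fat pad, spleen cells, or the tumours themselves set the B cell share stays open, as group and library are the same thing here. The same question bears on every ratio over vector in T cells, NK cells, phagocytes and dendritic cells. If the vector sample holds cells from outside the tumour, those ratios compare them as well, which was not tested.

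A set of 30 genes, among them Taf10, Jund, Bri3, Tmem160 and Socs1, is higher in each of the 5 classes measured in the paracaspase-deficient library. In cells not used to pick them most are higher over vector as well: 30 of 30 in the tumour-like cluster (median 2.07 log2), 24 of the 25 measured in plasmacytoid dendritic cells (1.63) and 14 of 15 in neutrophils (1.42), which is consistent with an effect on the whole library. Free RNA in the droplets supplies a median of 4.53% of their level, too little to make it. The median GC share of their first 500 bases is 67.8%, against 57.2% for expressed genes. But the most GC-rich genes as a group differ by a median of only 0.022 log2 over the 5 classes, from −0.10 in NK cells to 0.15 in T cells. In the tumour-like cluster they differ by 0.22 log2. Whether handling, sequencing or a response of every cell type to the tumour set them apart stays open, as group and library are the same.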

How the results depend on the processing

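The tests named here as chosen after the result was seen are the altered denominators, T sub-cluster 8, phagocytes without cluster 22, members above the free RNA level, and the length and GC trend. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Of the class share ratios, 243 of 333 stayed, 77 moved and 13 reversed. For list medians these were 476, 139 and 15 of 630, and for named genes 353, 91 and 0 of 444. Unless said otherwise the cause was not tested.

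B cells stayed lower in the wild-type than in the vector library under every alternative. The log2 ratio was −2.01 and became −1.69 with a mitochondrial limit of 5%, −1.91 with 20%, −1.81 with cells of 1000 UMIs or more, −1.92 at Leiden resolution 2, −1.87 without list genes in clustering, and −1.91 without unnamed and non-immune cells. For paracaspase-deficient over vector it was −1.51, and −1.66 with the 5% limit, −1.36 with 1000 UMIs, −1.43 at resolution 2 and −1.34 without list genes. Between the Malt1 libraries it was −0.50, and −0.034 with the 5% limit and −0.40 with 20%. The 5% limit keeps 5544 vector cells instead of 9696.

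Mononuclear phagocytes stayed higher than in the vector library. For wild-type the ratio of 3.03 became 2.44 with the 5% limit, 3.26 without list genes, 3.18 with a class per cell, 1.9596 without B cells and 1.07 without B and T cells. For paracaspase-deficient Malt1, 2.74 became 2.30, 2.91 without list genes, 1.78 without B cells and 1.10 without B and T cells. With wild-type against paracaspase-deficient Malt1, 0.29 became 0.14 with the 5% limit, 0.35 without list genes, 0.34 without unnamed and non-immune cells, 0.18 without B cells, and reversed to −0.033 without B and T cells.

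NK cells were more common over all cells but reversed without B and T cells, to −0.78 for wild-type, −0.64 for paracaspase-deficient Malt1 and −0.14 between them, as the denominator sets by construction. Under the 5% limit the last was −0.0022. Plasmacytoid dendritic cells (0.93 for wild-type over vector) reversed to −0.14 without B cells and −1.03 without B and T cells, and non-immune cells (0.87) to −0.20 and −1.09. Monocytes among phagocytes (−0.25 for wild-type, −0.26 for paracaspase-deficient Malt1) reversed to 0.13 and 0.0615 with the 5% limit, and for wild-type to 0.079 with the 20% limit and 0.0665 with 1000 UMIs.

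Regulatory-T-like cells stayed above the vector library. The wild-type ratio of 2.55 became 1.9589 with the 5% limit, 2.18 with 20%, 2.13 with doublets kept, 1.78 with a class per cell and 1.38 with sub-cluster 8 added. For paracaspase-deficient Malt1, 1.49 became 0.83 with a class per cell and 0.59 with sub-cluster 8. Gamma-delta-like cells (2.23 and 1.82) became 1.29 for wild-type with the 5% limit, and 0.36 and 0.26 with a class per cell. For regulatory-T-like cells of wild-type over paracaspase-deficient Malt1, 1.06 became 0.82 with the 5% limit and 0.79 with sub-cluster 8. Malt1 over all wild-type cells was 169 instead of 171 CPM with 1000 UMIs.

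Removing the length and GC trend reversed the ribosomal medians in B cells to −0.14, −0.073 and −0.065 for wild-type over vector, paracaspase-deficient over vector and wild-type over paracaspase-deficient. For wild-type over vector it also reversed the cytotoxic median of NK cells to −0.24 and, in phagocytes, MHC class I to −0.073, complement and lipid to −0.043 and hypoxia to −0.0215. It moved MHC class II to −1.14, and to −0.46 between the Malt1 libraries. There the interferon median reversed to −0.038 and hypoxia to −0.11, and the naive and memory median of T cells moved to −0.50. The interferon median was 0.42 over vector for wild-type and 0.42 for paracaspase-deficient Malt1.

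Equal weight per cell reversed the exhaustion median between the Malt1 libraries to 0.21. It moved naive and memory genes to −0.88, −0.32 and −0.46 in the same order of comparisons, and interferon to 0.50 and 0.40 over vector. A pseudocount of 5 CPM moved the regulatory T effector medians to 1.27 and 0.84 over vector.

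Median-of-ratios scaling moved naive and memory genes to −1.25 and −0.70 over vector, interferon gamma targets to −0.066 for wild-type over vector, interferon to 0.79 for wild-type over vector and 0.22 between the Malt1 libraries, and MHC class II to −0.77 and −0.057. It reversed MHC class I to 0.11 and complement and lipid to 0.045 between the Malt1 libraries, and NF-kB to 0.0051 for wild-type over vector.

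Without cluster 22 the interferon medians were 0.49 and 0.41 over vector, and MHC class II −0.996 for wild-type over vector and −0.25 between the Malt1 libraries. With free RNA subtracted MHC class II was −1.01 and −0.47, and interferon 0.085 between the Malt1 libraries. With members above the free RNA level only, MHC class II was −0.78 and −0.45, and the immunosuppressive median for paracaspase-deficient Malt1 over vector reversed to −0.036. With no minimum beyond 1 UMI, neutrophil granule genes reversed to −0.14 for wild-type over vector.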

Other observations

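The tests of cluster shares below were chosen only after the clusters were seen, and none was planned. The list medians below come from classes other than the one set for each list, and were picked after the values were seen.

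Patrolling-type monocytes with Ace, Ear2, Adgre4 and Treml4 formed cluster 21, with 97 vector, 131 wild-type and 103 paracaspase-deficient cells, the last pair 1.17% and 1.10% of their libraries.

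Cells with Vcam1, Slc40a1, Fcna, Cd5l and Spic, genes of iron-recycling macrophages, formed cluster 32 and made up 0.670% (0.518 to 0.854) of vector, 0.205% (0.130 to 0.307) of wild-type and 0.161% (0.0900 to 0.265) of paracaspase-deficient cells. Its top genes also include Gata2 and Slc45a3, and with the 5% mitochondrial limit a like cluster was named mast cell or basophil. At resolution 0.5 a cluster with Vcam1, Fcna and Spic but without Gata2 among its top genes held 37, 4 and 1 cells. Cluster 32 may thus mix cell types, and its share is not that of macrophages alone. Iron-recycling macrophages sit in the red pulp of the spleen. If they make up the difference, the higher share in the vector library may have the same source as the marginal zone B cell list at −0.92 log2. Epithelial markers summed to 34.5, 9151 and 860 CPM over the 65 vector, 23 wild-type and 15 paracaspase-deficient cells of cluster 32. These sums do not tell how many cells hold the markers, which leaves mixed droplets open.

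Dividing B cells and plasmablasts with Mki67, Ighg1 and Jchain formed cluster 24, at 1.57%, 0.596% and 0.740% of all cells. Cells of low depth differ in kind: cluster 20, with Ebf1 and Ighm and a median of 628 UMIs, holds 236, 86 and 28 cells, and cluster 11, with Spp1 and Ccl2 and a median of 874 UMIs, 37, 585 and 334.

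Dendritic cells also held more interferon-response RNA in the Malt1 libraries, with list medians of 0.81 log2 for wild-type and 0.89 for paracaspase-deficient Malt1 over vector, both at percentile 100, and Isg15 at 596, 2021 and 1517 CPM. Their NF-kB and inflammatory list was lower, at −0.67 and −0.33 (percentiles 0.02 and 0.06). Il12b, the T cell polarizing cytokine of dendritic cells, stood at 250, 141 and 210 CPM, while Ccl22, which draws regulatory T cells, stood at 494, 707 and 615 CPM.

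NK cells had higher medians of the hypoxia and glycolysis list, at 0.76 and 0.72 log2 over vector, and of the proliferation list, at 0.46 and 0.45. T cells had higher cytotoxic effector genes, at 1.20 and 1.14. Each of these medians is at percentile 100.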
